A study of Mus musculus with 6 samples.

How the data were processed

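RNA of TM3 cells, an established mouse Leydig cell line of testicular origin, was measured by RNA sequencing in 6 libraries, 3 from control cells and 3 from cells overexpressing A20. Per the labels' protocols, total RNA was taken with a column kit and the libraries were made with a SMARTER mRNA kit. How A20 was overexpressed, from which species its sequence came and whether the 3 libraries of a group were separate cultures are not stated, so the spread within a group may be narrower than that between independent experiments.

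The deposited count table holds whole-number counts for 54532 genes, with the gene's symbol, position, length and biotype, and was used as deposited. Per the submitters' processing notes, the genome build was GRCm38, also called mm10. The aligner, the counter and the strand setting are not stated, so reads of overlapping genes on opposite strands could not be told apart. Of the gene identifiers, 54495 were also in GENCODE M21, an annotation of the same build, and 53585 of these had the same chromosome, start and end. The deposited FPKM values were found to equal the count divided by the gene length and by a scaled library size made by the authors. That library size was in 1 ratio to the median-of-ratios size factors of the counts in each of the 6 libraries. The FPKM served only in alternatives. Total counts ran from 13841287 to 16917979 per library. A gene without a count in a library could lie at up to 0.177 to 0.217 CPM, the level of 3 counts. These floors cover counting error only, since the reads carry no molecular identifiers.

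The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) with TMM normalization, the default expression filter by group, robust fitting and Benjamini-Hochberg adjustment over all genes kept, with 0.05 as the threshold. The design held the group alone. CPM values use the library's total count, and log2 fold changes are A20 overexpression over control. The standard error given beside a log2 fold change is approximate, being its size divided by the square root of the F statistic. The 23 gene lists were fixed before the data were examined, as were the comparison, the first set of other settings and the rule for naming genes. Lists with at least 5 genes kept were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with the directional test of fry. The mixed test of fry, which asks for change in either direction, was computed as well. The remaining 4 lists, of macrophage, Sertoli cell, germ cell and endothelial markers, kept 3 genes each and are given by their members. Of the list symbols, 3 were not in the count table under the name used.

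The rule named Tnfaip3, which encodes A20. It then took up to 10 protein-coding genes per direction with the largest fitted change, among those past the threshold, without overlap between the groups in CPM and with a mean of at least 5 CPM in the higher group. From each list it took up to 3 members with the smallest adjusted p past the threshold, or else the most abundant member. Some genes that this would name are not reported here. The fit on all 6 libraries is the planned one. Leaving out each library in turn was planned as well. The fit without control replicate 1 was singled out after the data were examined, because that library stood apart from the others. The naming rule and the alternatives were applied to this fit of 5 libraries too.

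The other settings fixed at the start were median-of-ratios (RLE) and upper-quartile factors, library size alone, no filter on low counts, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), the former also on genes with a mean FPKM of at least 1, a replicate block and a fit without robust estimation. Added after the data were examined were limma-voom with quality weights per library, offsets for GC content and length, also with the block, and a test of protein-coding genes alone. GC content came from the longest transcript in GENCODE M21 and was known for 99.9% of the genes in the 5-library fit. Sample labels were also regrouped in each possible way.

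The procedure was tested on simulated counts drawn from the real libraries' means, sizes and dispersions. On 13350 genes in the design of 6 libraries it recovered 45% of genes changed 2-fold and 96% of those changed 4-fold. On 13658 genes in the design of 5 libraries it recovered 82% and 98%. The changes were planted in genes with a mean of at least 5 CPM, so recovery below that level was not tested. All libraries were drawn from the same gene means, so a library that stands apart, as control replicate 1 does, was not simulated. Genes inside introns were found with GENCODE M21 in Python 3.11.15, and a difference of medians was tested in R with 100000 permutations. On a simulated shift of -0.6 that test recovered -0.73.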

Results

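The series asked how overexpression of A20 changes gene expression in TM3 cells, a mouse Leydig cell line. Leydig cells are the androgen-producing cells of the testis, and A20, the product of Tnfaip3, is a ubiquitin-editing enzyme that restrains NF-kB signalling and cell death. Poly(A) RNA sequencing counts were available for 3 control and 3 A20-overexpressing libraries. Total counts were 15349354, 14346445 and 13841287 in control replicates 1, 2 and 3, and 16917979, 15654179 and 15097570 in A20-overexpressing replicates 1, 2 and 3.

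Tnfaip3 was the most direct check of the labels. The gene (ENSMUSG00000019850, GRCm38 chromosome 10, 19000910 to 19015657, minus strand) stood at 41.0, 33.7 and 43.6 CPM in the A20-overexpressing libraries, above each control library, at 30.9, 11.9 and 15.2 CPM. The means were 39.4 CPM ± 5.15 (SD, n = 3) and 19.4 CPM ± 10.2 (SD, n = 3). Over all 6 libraries the log2 fold change was 1.08 ± 0.30 (SE), which did not pass edgeR's quasi-likelihood test (unadjusted p = 0.00575, adjusted p = 0.331). Control replicate 1 held the highest control value. Without it, Tnfaip3 was 2.84-fold higher, with a log2 fold change of 1.51 ± 0.19 (SE) and an adjusted p of 0.000256 in edgeR. Counts on this gene register a transgene only where it carries mouse Tnfaip3 sequence, which is not stated.

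Control replicate 1 expressed key genes of steroid production that had few or no counts in the other 5 libraries. Cyp11a1, the enzyme of the first step of steroid synthesis, was at 851 CPM there and at 0 to 0.144 CPM in the others. Star, which carries cholesterol into mitochondria, was at 497 CPM against 2.52 to 4.54 CPM, and Hsd3b1 was at 532 CPM with no count in the others. Nr5a1, the transcription factor that drives steroidogenic genes, was at 125 CPM against 0.0697 to 0.596 CPM. The electron carrier gene Fdx1 was present in the others, at 19.2 to 22.5 CPM against 169 CPM, and the lipoprotein receptor gene Scarb1 was lower in control replicate 1, at 106 CPM against 170 to 210 CPM. Across 12548 genes, which are not independent replicates, log2 CPM of this library correlated with the others at a Pearson r of 0.854 to 0.866, whereas the other 5 correlated with one another at 0.967 to 0.992. The 2 groups below are therefore compared both with all 6 libraries, as planned, and without control replicate 1. The remaining controls did not form a tight group. By chi-square per degree of freedom between the counts of a pair, where smaller is closer, control replicates 2 and 3 stood at 34.3. Control replicate 3 stood at 27.3 to 32.2 from the A20-overexpressing libraries, closer than to control replicate 2. Control replicate 2 stood at 43.1 to 50.3 from them, and they stood at 8.94 to 17.3 from one another.

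**Figure D1:**
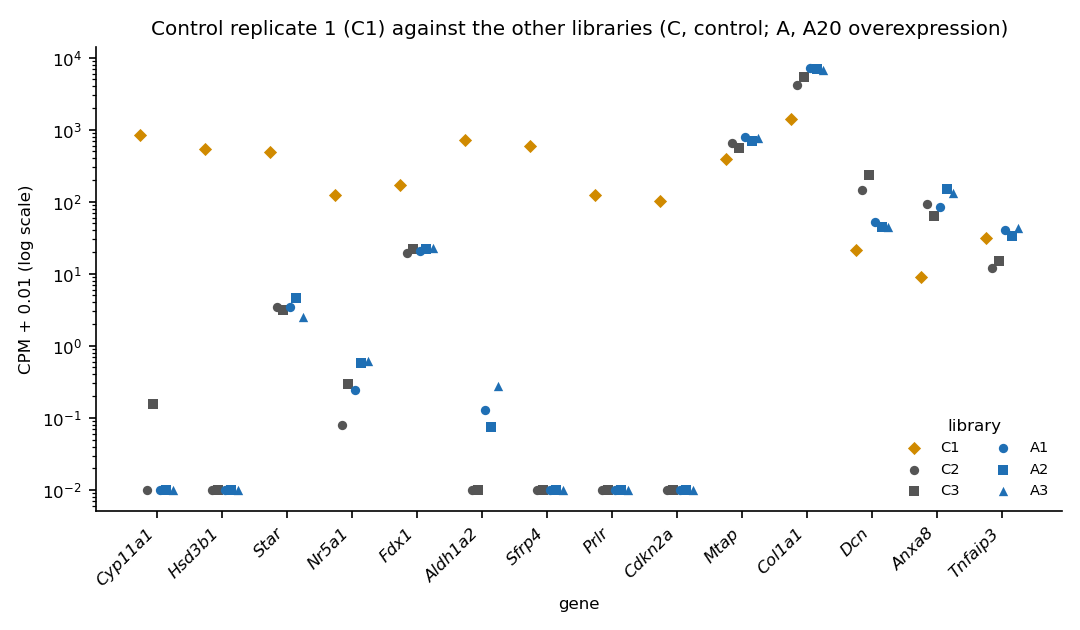
CPM plus 0.01 on a log axis for 14 genes, with each point a library (C, control; A, A20 overexpression). Control replicate 1 lies at 851 CPM for Cyp11a1 and at 1410 CPM for Col1a1, away from the other 5 libraries on both sides.

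With all 6 libraries, the comparison of A20 overexpression with control singled out Limch1, an actin-associated protein gene, and Rpl34-ps1, a processed pseudogene of a ribosomal protein. Limch1 (ENSMUSG00000037736, chromosome 5, 66745827 to 67057158) rose from 1.42 CPM ± 0.425 (SD, n = 3) to 16.4 CPM ± 5.02 (SD, n = 3), 11.8-fold. Rpl34-ps1 (ENSMUSG00000068396, chromosome 6, 71124610 to 71124963) fell from 64.0 CPM ± 12.2 (SD, n = 3) to 13.6 CPM ± 2.91 (SD, n = 3); it was outside the naming rule, and its reads can be shared with the parent gene and other copies. Each had an adjusted p of 0.0498 in edgeR, and these were the 1 gene higher and the 1 gene lower among 13350 tested, both by over 2-fold. An unadjusted p under 0.05 was found for 1341 genes (10%). Groups did not overlap in CPM for 16.9% of genes, where chance gives 10%. DESeq2 called 163 genes and limma-voom 0, and edgeR called 628 genes without control replicate 1 and 0 without any other single library.

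Among the fixed lists with all 6 libraries, 4 of 19 passed camera with a preset correlation. Interferon-stimulated genes (19 kept, median log2 fold change -0.56, adjusted p = 0.00218), cholesterol synthesis and uptake (25 kept, median -0.45, adjusted p = 0.00296) and DNA replication (29 kept, median -0.35, adjusted p = 0.014) lay lower. Genes of the integrated stress response and of unfolded proteins lay higher (27 kept, median 0.12, adjusted p = 0.014). With an estimated correlation each of these had an adjusted p = 0.933, and without control replicate 1 the preset-correlation values were 0.0873, 0.0573, 0.72 and 0.679. The same lists also set control replicate 1 apart: its median log2 ratio to the other 5 libraries was 1.25 for interferon-stimulated genes, 0.51 for cholesterol genes, 1.10 for DNA replication and -0.34 for the stress response. Steroidogenesis had a median of -1.01 with all 6 libraries (camera adjusted p = 0.134) and 0.05 without that library (adjusted p = 0.64). No list member passed edgeR over all genes with all 6 libraries; adjusted over the list alone, A20 partners had 1 member higher and 1 lower, NF-kB target genes 1 higher and 2 lower, oxidative stress 1 higher and 1 lower, the stress response and the actin list 1 higher each, MHC class I presentation 2 lower, and interferon, steroidogenesis, Sertoli and ribosomal protein lists 1 lower each.

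The most abundant member kept of each list did not pass edgeR's test with all 6 libraries. For the NF-kB target Vcam1 the log2 fold change was -0.05 ± 0.16 (SE), for the cyclin-dependent kinase inhibitor Cdkn1a 0.07 ± 0.50 (SE), for the apoptosis regulator Mcl1 -0.22 ± 0.22 (SE) and for the chaperone gene Hspa5 -0.03 ± 0.37 (SE). B2m, the light chain of MHC class I, had the smallest adjusted p of these members, 0.31 in edgeR, with a log2 fold change of -0.78 ± 0.20 (SE, unadjusted p = 0.0044) and no overlap between the groups. Values of the others were Ube2d3 -0.27, Bst2 -0.56, Por -0.05, Srebf2 0.15, Top2a -0.10, Rrm1 0.03, Gsdmd 0.20, Ftl1 0.54, Ndrg1 0.18, Fn1 0.39, Tpm1 -0.07, Egfr 0.24, Cd68 0.30, Ctsl -0.23, Sycp1 0.21, Egfl7 0.29, mt-Co1 0.11 and Rplp0 0.02, with adjusted p from 0.31 to 0.987 over all the members given here.

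Without control replicate 1, RNA of Sfrp2, Cd34, Ptn, Pmaip1 and Tet2 was lower in cells overexpressing A20, and RNA of Limch1 and Ms4a2 was higher. Sfrp2, a secreted Wnt antagonist, fell from 9.10 CPM ± 1.33 (SD, n = 2) to 0.269 CPM ± 0.119 (SD, n = 3), 33.2-fold. Cd34, a surface sialomucin, fell 7.33-fold and Ptn, the growth factor pleiotrophin, 5.31-fold. Pmaip1, which encodes the pro-apoptotic protein Noxa, fell 12.5-fold, and Tet2, a 5-methylcytosine dioxygenase, fell 4.8-fold. Limch1 rose 13.1-fold, and Ms4a2, a subunit of the high-affinity IgE receptor, rose from 52.7 CPM ± 11.4 (SD, n = 2) to 202 CPM ± 55.9 (SD, n = 3).

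**Figure D2:**
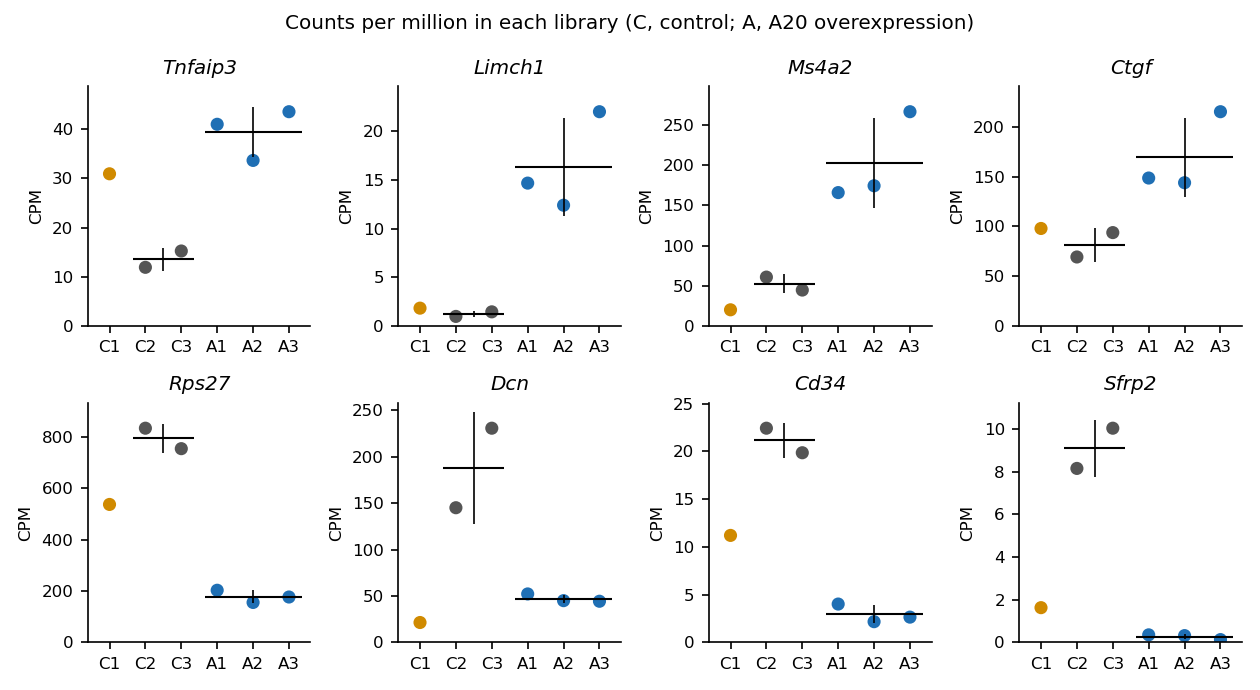
CPM of 8 genes in each library on linear axes from 0 (C, control; A, A20 overexpression). Horizontal lines are means and vertical lines SD of control replicates 2 and 3 and of the 3 A20-overexpressing libraries; control replicate 1 stands alone, for example at 30.9 CPM for Tnfaip3.

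In this fit of 5 libraries, edgeR called 262 genes higher and 366 lower among 13658, 94 and 194 of them by over 2-fold. The rest of the 10 protein-coding genes that fell most were Il13ra1, a subunit of the interleukin-13 receptor (30.8-fold), Trim44 (20.3-fold), Slco5a1 (10.5-fold), the inositol synthesis gene Isyna1 (8.85-fold) and Rps27 (4.57-fold), a ribosomal protein gene at 794 CPM in control. In A20 overexpression Il13ra1 averaged 0.168 CPM, Trim44 0.458 CPM and Slco5a1 0.531 CPM. The size of these falls, like that of Sfrp2 at 0.269 CPM, therefore rests on few counts. The rest of those that rose most were Rpl10-ps3 (6.94-fold), Serpinb7 (5.63-fold), Cage1 (3.79-fold), Gm5662 (3.69-fold), the pseudokinase gene Styk1 (3.60-fold), Nutf2-ps1 (3.46-fold), the growth factor gene Fgf18 (3.43-fold) and Endod1 (3.35-fold), at 5.53 to 12.5 CPM in A20 overexpression. Adjusted p in edgeR ran from 5.44e-07 for Rps27 to 0.0133 for Endod1 over these 20 genes. Rpl10-ps3, Nutf2-ps1, Gm5662 and Rps27 have near-identical copies among which reads can be split. In control replicate 1, Trim44 stood at 126 CPM, Isyna1 at 67.3 CPM and Tet2 at 39.4 CPM, well above the other controls, and Endod1 at 20.3 CPM lay above the A20-overexpressing libraries, with Fgf18 at 7.04 CPM within their range. Other genes that fell were low in control replicate 1: Pmaip1 at 0.847 CPM, Sfrp2 at 1.63 CPM and Slco5a1 at 1.43 CPM, against at least 6.94, 8.15 and 5.13 CPM in the other controls and at most 0.795, 0.355 and 1.00 CPM in A20 overexpression.

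The number of genes called in this fit depends on single libraries. edgeR called 142, 191 and 160 genes without A20-overexpressing replicate 1, 2 or 3. Of the 628 genes called in this fit, 22.3%, 28.5% and 24.8% were among these, with the same sign. Leaving out control replicate 2 or control replicate 3 leaves 1 control, so that the spread in these fits comes from the A20-overexpressing libraries alone. Their totals of called genes therefore do not show how many of the same calls hold. Control replicate 1, which took no part in the fit, lay on the control side of the A20-overexpression mean for 267 of the 366 genes that fell and for 145 of the 262 that rose. For 21 of the 54 called genes that the naming rule gives in this fit it lay within (6) or beyond (15) the range of the A20-overexpressing libraries, away from the other controls. The share on the control side over all genes tested was not computed, and control replicate 1 stood apart in many genes. These counts therefore do not test the calls.

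**Figure D3:**
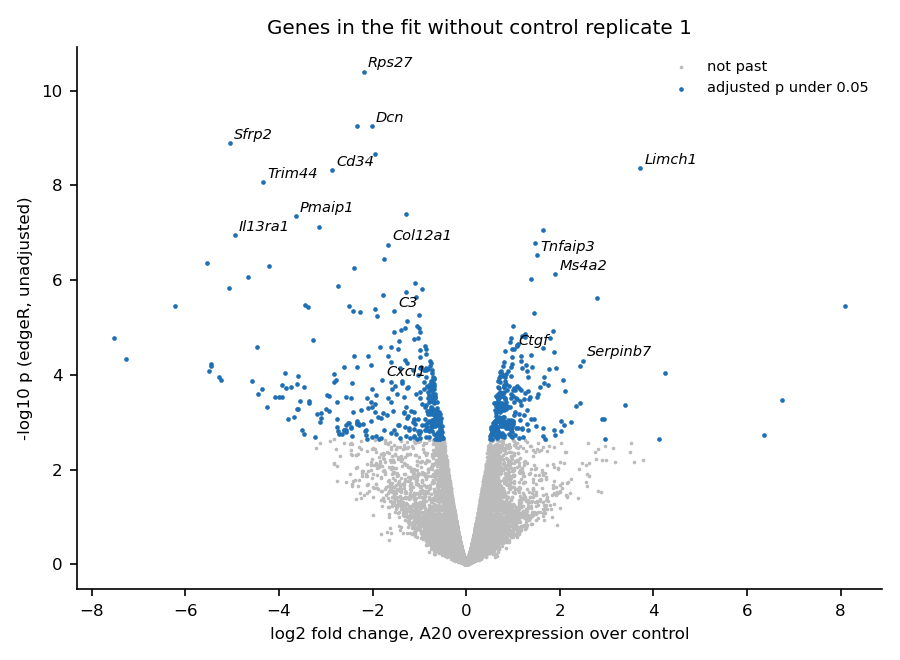
Log2 fold change against -log10 of edgeR's unadjusted p for 13658 genes in the fit without control replicate 1, with genes past the adjusted threshold in blue. The gene with the smallest p, Rps27, is among the 366 that fell, and 262 rose.

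Extracellular matrix genes moved in both directions in the 5-library fit, with 4 lower, 1 higher and 21 of 26 not past the test. Dcn, the proteoglycan decorin, fell from 188 CPM ± 60.6 (SD, n = 2) to 47.2 CPM ± 4.37 (SD, n = 3), and Col12a1, a fibril-associated collagen, fell 3.16-fold. Thbs1, the matricellular protein thrombospondin-1, rose 1.60-fold. Targets of YAP and SRF had 2 members higher, 0 lower and 21 not past: Ctgf rose 2.03-fold and Cnn2, a calponin, 1.53-fold. Among growth factor and hormone receptors and their ligands, Fgfr1 fell 1.54-fold and Igf1 2.16-fold, with 15 of 17 not past. In control replicate 1, Dcn (21.4 CPM), Fgfr1 (86.2 CPM) and Igf1 (1.43 CPM) lay below each A20-overexpressing library and Cnn2 (249 CPM) above each, while Col12a1 (15.2 CPM) and Thbs1 (192 CPM) lay within their range, and the median log2 ratio of that library to the other 5 was -1.23 over the matrix list.

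Genes of inflammation and cell death moved singly. Of 26 NF-kB target genes, 3 fell, 1 rose and 22 did not pass. Complement C3 fell 2.92-fold, the chemokine gene Cxcl1 3.49-fold, and Mmp9 fell from 1.86 to 0.144 CPM. C3 stood at 22.2 CPM in control replicate 1, below the A20-overexpressing libraries. Among A20 partners and ubiquitin-editing genes, Rbck1, part of the linear ubiquitin ligase, rose 1.65-fold and Birc2, the ubiquitin ligase cIAP1, fell 1.59-fold, with 22 of 24 not past. Of 20 p53 targets, Pmaip1, Btg2 (1.76-fold) and Fas, a death receptor (2.28-fold), fell and 1 rose. In control replicate 1 these stood at 0.847, 16.1 and 8.47 CPM, near or below the A20-overexpressing libraries, and the median log2 ratio of that library to the other 5 was -0.91 over the p53 targets. Birc2 and Fas were also the 2 apoptosis regulators that fell, with 25 of 27 not past. In the necroptosis and pyroptosis list edgeR called 0 of 8, and Gsdmd, its most abundant member, had a log2 fold change of -0.01 ± 0.14 (SE). Oasl2 fell 3.79-fold and was the 1 interferon-stimulated gene of 19 called, and it stood at 30.6 CPM in control replicate 1. B2m (1.59-fold) and the proteasome activator gene Psme2 (1.47-fold) fell among 12 MHC class I genes.

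Metabolic and stress genes held smaller changes. The antioxidant genes Srxn1 and Nqo1 rose 1.61-fold and 1.60-fold, while Gstp1, at 2.37 CPM in control and with a close paralog, fell 5.67-fold; 21 of 24 oxidative stress genes did not pass. In glycolysis and hypoxia, Pfkl rose 1.54-fold and Eno1 1.46-fold, and Car9 fell 1.77-fold, with 21 of 24 not past. Trib3 rose 1.75-fold and Manf fell 1.62-fold among 27 genes of the integrated stress response and unfolded proteins. Stard4, a sterol carrier gene, fell 1.60-fold among 26 genes of cholesterol synthesis and uptake, of which 24 did not pass. With GC and length offsets edgeR called neither Eno1, whose log2 fold change shrank from 0.55 ± 0.15 (SE) to 0.37 ± 0.13 (SE, adjusted p = 0.0823), nor Stard4, which went from -0.67 ± 0.19 (SE, adjusted p = 0.0494) to -0.62 ± 0.18 (SE, adjusted p = 0.0588). In steroidogenesis, Akr1c14 fell 4.31-fold and 17 of 18 did not pass. The mitochondrially encoded mt-Nd4, mt-Cytb and mt-Nd6 rose 1.73-fold, 1.76-fold and 1.68-fold, with 9 of 12 not past, and of 30 cytosolic ribosomal proteins Rps27 and Rps18 (1.68-fold) fell. In control replicate 1, mt-Nd4 (1437 CPM), mt-Cytb (1875 CPM), mt-Nd6 (707 CPM), Eno1 (1862 CPM), Pfkl (352 CPM) and Srxn1 (105.5 CPM) lay above each of the other libraries, Manf (295 CPM) lay below each A20-overexpressing library, and Car9 (36.9 CPM) and Stard4 (219 CPM) lay within their range.

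Cell cycle and DNA replication lists had 0 of 26 and 0 of 29 members past edgeR's test without control replicate 1; Top2a had a log2 fold change of -0.36 ± 0.16 (SE, unadjusted p = 0.04) and Rrm1 of -0.13 ± 0.15 (SE). Markers of other testis cells were few: 3 genes kept in each list. Clu, the Sertoli cell marker clusterin, fell 2.47-fold but stood at 221 CPM in control replicate 1. The macrophage marker Cd68 (log2 fold change -0.21), the germ cell marker Sycp1 (0.10) and the endothelial marker Egfl7 (-0.15) did not pass. Among the 19 lists tested without control replicate 1, 0 passed camera after adjustment, 5 had an unadjusted p under 0.05, and 0 passed with an estimated correlation or with fry's directional test; the smallest adjusted p was 0.0573, for cholesterol synthesis and uptake (median log2 fold change -0.32; adjusted p = 0.791 with an estimated correlation). The mixed test of fry, which asks for members changed in either direction, passed 13 of the 19 lists without control replicate 1. With all 6 libraries it passed 1, NF-kB target genes (fry adjusted p = 0.0246). This test does not set a list against the other genes. Without control replicate 1, 21.6% of all genes tested had an unadjusted p under 0.05 in edgeR, so a pass is not particular to a list. Glycolysis and hypoxia, extracellular matrix and cytosolic ribosomal proteins had the smallest mixed fry adjusted p in that fit, 0.00177 each. NF-kB target genes had 0.00698 there. Adjusted over the list alone, oxidative stress and glycolysis each had 6 members higher and 2 lower, the matrix list 2 higher and 5 lower, cholesterol genes 5 lower, NF-kB targets 3 higher and 4 lower, and p53 targets 2 higher and 4 lower.

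**Figure D4:**
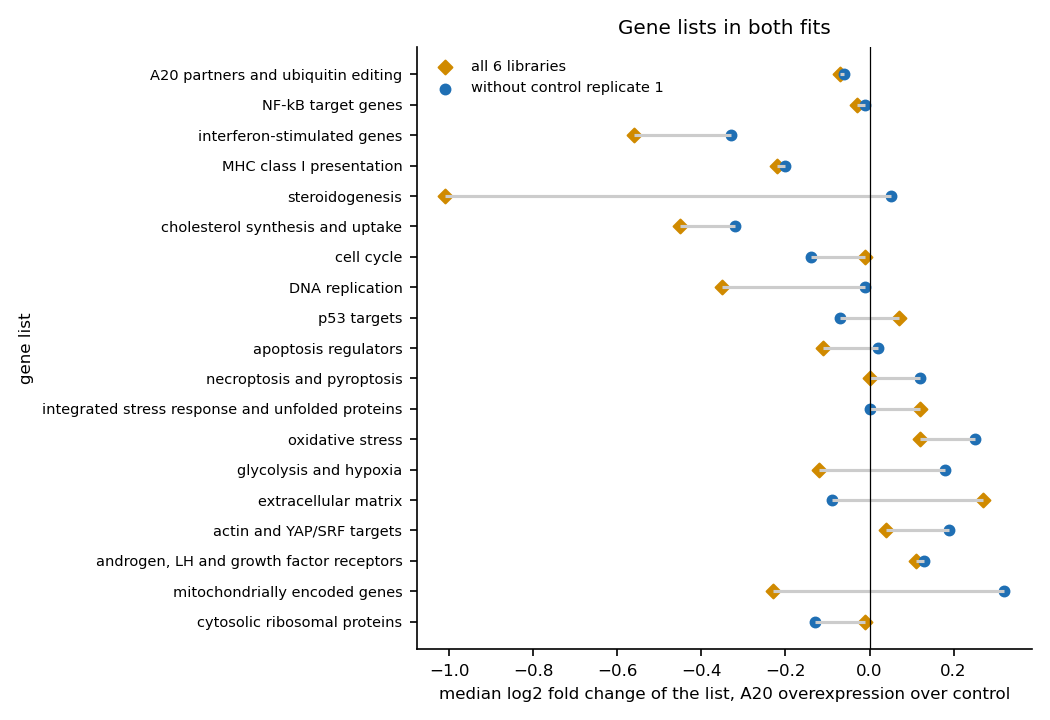
Median log2 fold change (A20 overexpression over control) of each of the 19 tested gene lists, with all 6 libraries and without control replicate 1. Steroidogenesis moves most, from -1.01 to 0.05.

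TEC and sense intronic genes that passed the test in the 5-library fit were nearly all lower in A20 overexpression. Of 363 genes annotated as TEC, which are single-exon transcripts awaiting experimental support, 60 fell and 1 rose, and of 51 sense intronic transcripts 12 fell and 0 rose. Antisense genes had 11 of 375 lower and 0 higher, lincRNAs 9 lower and 3 higher of 289 and processed pseudogenes 13 lower and 6 higher of 737, whereas protein-coding genes had 246 lower and 248 higher of 11379. TEC genes took 0.143% and 0.161% of counts in control replicates 2 and 3 and 0.08% to 0.0897% in the A20-overexpressing libraries, and control replicate 1 was at 0.119%. The nuclear long non-coding RNA Malat1, named after its values were seen, fell from 5564 CPM ± 1310 (SD, n = 2) to 1467 CPM ± 253 (SD, n = 3), 3.87-fold, with an adjusted p of 5.95e-06 in edgeR.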

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

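The fit without control replicate 1, quality weights per library, offsets for GC content and length and the test of protein-coding genes alone were chosen after the data were examined. Tnfaip3 was higher in A20 overexpression under each alternative run. With all 6 libraries its log2 fold change ran from 0.88 to 1.51 when single libraries were left out, passing edgeR's test without control replicate 1, and was 1.42 with quality weights, where limma's test called it (adjusted p = 0.00249, against 0.000256 to 0.99 over the other alternatives). In the 5-library fit it ran from 1.38 to 1.65 with single libraries left out and missed the threshold on log2(FPKM + 1), at 1.14, and on log2(FPKM + 0.1), at 1.46; the cause was not tested.

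With all 6 libraries, 1 gene was called in each direction, both over 2-fold. The counts were 0 with upper-quartile factors, library size alone, limma-voom, each of the 3 FPKM fits, the fit without robust estimation, GC and length offsets with or without the replicate block, and protein-coding genes only. They were 7 higher and 16 lower with no filter on low counts (7 and 15 by over 2-fold), 56 and 107 with DESeq2 (26 and 86) and 134 and 279 with quality weights (51 and 175). Leaving out 1 library gave 0 to 262 higher, 0 to 366 lower, 0 to 94 higher by over 2-fold and 0 to 194 lower by over 2-fold, the upper values without control replicate 1 and 0 without each other library. Of the 19 lists, 4 passed; leaving out 1 library gave 0 to 5, and an estimated inter-gene correlation and fry's directional test each gave 0.

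In the 5-library fit, 262 and 366 genes were called, 94 and 194 by over 2-fold. No filter on low counts gave 580 and 593 (179 and 299). GC and length offsets gave 457 and 670. The FPKM fits gave 0 and 0, except 11 higher and 24 lower (10 and 23) on genes with a mean FPKM of at least 1. A filter of 1 CPM in 3 libraries left 111 lower by over 2-fold. With 2 controls it drops each gene below 1 CPM in all A20-overexpressing libraries, Sfrp2 among them. Protein-coding genes only left 98, as genes of other biotypes, whose calls were mostly lower, were not tested. Leaving out 1 library gave 45 to 1290 higher, 93 to 1133 lower, 30 to 524 and 82 to 296 by over 2-fold; each A20-overexpressing library lowered the counts when left out, and control replicate 3 raised them. Without control replicate 2 or 3 this fit has 1 control, and its spread comes from the A20-overexpressing libraries. Lists past the test were 1 with library size only, 2 with no filter on low counts, 2 with 1 CPM in 3 libraries and 0 to 3 when 1 library was left out, against 0.

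Whether replicate numbers pair the libraries could not be told. Deviations from the group means correlated at 0.026, 0.115 and -0.039 for numbers 1, 2 and 3, and 1 of 6 libraries correlated best with its own number. The control mean includes control replicate 1, so the distance of that library weighs on the deviations of each control. With the replicate block 2 genes were called over all 6 libraries, and in the 5-library fit 797, among them 406 higher (175 by over 2-fold). In the latter, number 1 has no control, so the contrast rests on numbers 2 and 3 alone.

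Values that changed sign belong to genes that none of these fits called. With all 6 libraries, leaving out 1 library gave log2 fold changes of -0.125 to 0.036 for Vcam1, -0.16 to 0.11 for Por, -0.035 to 0.281 for Srebf2, -0.36 to 0.19 for Top2a, -0.13 to 0.22 for Rrm1, -0.36 to 0.57 for Cdkn1a, -0.005 to 0.319 for Gsdmd, -0.35 to 0.32 for Hspa5, -0.28 to 0.48 for Ndrg1, -0.001 to 0.824 for Fn1, -0.21 to 0.71 for Cd68, -0.15 to 0.61 for Egfl7, -0.015 to 0.276 for mt-Co1 and -0.057 to 0.121 for Rplp0. Quality weights gave 0.00 for Vcam1, -0.026 for Srebf2, -0.05 for Rrm1, -0.277 for Cdkn1a, -0.004 for Gsdmd, -0.165 for Ndrg1, -0.18 for Cd68, -0.054 for Sycp1, -0.13 for Egfl7 and -0.022 for Rplp0. GC and length offsets gave 0.032 for Vcam1, -0.059 for Srebf2, -0.065 for Cdkn1a and -0.001 for Rplp0, and with the replicate block 0.043 for Vcam1, -0.035 for Srebf2, 0.018 for Top2a and 0.106 for Hspa5. For Hspa5, limma-voom gave 0.078, the FPKM fits 0.096, 0.097 and 0.096 and the replicate block 0.085, and library size only gave -0.01 for Rplp0. In the 5-library fit, leaving out 1 library gave -0.285 to 0.053 for Rrm1, -0.061 to 0.056 for Gsdmd and -0.151 to 0.402 for Sycp1, which was -0.06 with the replicate block; Gsdmd was 0.003 with upper-quartile factors, 0.028 with library size only and 0.023 with no filter. The cause was not tested.

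At this depth, genes without a count in a library lie below 0.177 to 0.217 CPM, so larger folds among genes of few CPM rest on few counts.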

Other observations

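The tests on control replicate 1 and the interval of the receptor ratio from values per library were chosen after the result was seen, and those on GC content, receptor genes and introns before they were run. Control replicate 1 carried a broad set of transcripts that the other 5 libraries lacked. Of 27 steroidogenesis genes in the count table, 13 were over 4-fold higher there and 0 over 4-fold lower, and 23 of the 27 reached 1 CPM there against 16 in the mean of the other 5. Aldh1a2, a retinoic acid synthesis gene, was at 718 CPM against 0 to 0.265 CPM, the Wnt antagonist gene Sfrp4 at 589 CPM and the imprinted long non-coding RNA Meg3 at 304 CPM, both without a count elsewhere. The prolactin receptor gene Prlr was at 125 CPM and Lhcgr, the luteinizing hormone receptor gene, at 7.36 CPM, with 0 counts of each in the other 5. Col1a1 was at 1410 CPM against 4180 to 7150 CPM, and Mmp2 at 90.6 CPM against 357 to 481 CPM.

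The cell cycle inhibitor genes Cdkn2a and Cdkn2b had 1549 and 445 counts in control replicate 1 and 0 in the other 5 libraries, so that their level over the pooled counts of these is at most 0.04 CPM. The neighbouring Mtap was at 396 CPM in control replicate 1 and 548 to 782 CPM in the others, and Klhl9 at 72.9 CPM against 49.0 to 81.6 CPM. Both genes lie on chromosome 4, and counts alone do not tell a loss of the locus from silencing. Interferon-stimulated genes also stood apart, with 25 of 33 over 2-fold higher in control replicate 1 and 0 over 2-fold lower. Control replicate 1 had counts on 22961 genes against 18328 to 20228 in the others, and 45.1 CPM summed over olfactory and vomeronasal receptor genes against 10.8 to 15.4 CPM.

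The first pattern is that control replicate 1 stands apart. Other cells as the source of less than 50% of its RNA are argued against, if its TM3 cells match those of the other libraries: among 3836 genes at 50 CPM or more in each of the other 5, 80 lay below 50% of the lowest of these, where each of the 5 set against the other 4 gave 0 to 10. Other, steroidogenic cells as the source of most or all of the RNA remain a candidate explanation, with 123 genes at 10 CPM or more there and no count in the other 5. Of 4470 genes at 50 CPM or more in the mean of the other 5 libraries, 0 lay below 1/16 of that level in control replicate 1, against 72 of 4889 the other way; a remaining share of TM3 RNA or a related cell that expresses the TM3 genes would each give this, so most and all stay open. Also open and not tested are a TM3 culture in another state, a mislabelled sample and genomic DNA as part of the library, with 45.1 CPM on receptor genes, and no biological explanation was tested, since the label puts this library in the group of control replicates 2 and 3.

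The second pattern is the set of genes called without control replicate 1. Control replicate 2 carried a trend with GC content, from 0.22 log2 units above the mean of the 5 libraries in the fifth of genes with the lowest GC to -0.27 in the fifth with the highest. Among the 2729 genes with the lowest GC, 34 were called higher and 132 lower in A20 overexpression. Among the 2729 with the highest GC, 91 were called higher and 36 lower, so the direction of calls went with this trend. With offsets for GC content and length, 93.3% of the called genes (586 of 628) were called again, each with the same sign. This argues against the GC trend as the whole cause. How far the trend set the direction of the calls stays open. A difference between control and A20-overexpressing cultures other than A20 stays open, since the labels give no batch or day.

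With 10 splits of the 5 libraries into 2 and 3, a share under 0.05 cannot be reached; the real split gave 262 genes higher and 366 lower, and the highest of the others gave 1 and 0. Splits of all 6 libraries are also 10 and cannot reach it either: the real split gave 1 gene higher and 1 lower, each by over 2-fold, and the highest other 0 in each case. For the gene lists, the real split gave 4 and the highest other 11, and in all 10 splits at least 4 lists passed. A structure among the libraries and a preset inter-gene correlation of 0.01 that is too low (estimates were 0.172 to 0.38 for the 4 lists that passed, and 0 lists passed with them) were not told apart. In the splits of the 5 libraries the real one gave 0 lists and the highest other 6.

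The third pattern is the lower level of TEC and sense intronic transcripts in A20 overexpression without control replicate 1. Genomic DNA in control replicates 2 and 3 is narrowly argued against: the CPM summed over 1979 olfactory and vomeronasal receptor genes in these was 0.918 times that in A20 overexpression (exact Poisson 95% interval 0.802 to 1.05, which covers counting error only; from the spread between libraries, on log values, the ratio was 0.924 with a 95% interval of 0.581 to 1.47, n = 2 and 3, just below the 1.5 that was set as the ratio genomic DNA would need). More unspliced RNA in the control libraries may account for part of it. The 229 TEC genes inside introns of protein-coding genes on the same strand had a median log2 fold change of -1.07. It was -0.40 for the 114 that overlapped no protein-coding gene on the same strand, a difference of -0.67. These 114 can still lie inside genes of the opposite strand or non-coding genes. The two-sided permutation p was 1e-05, the smallest that 100000 permutations can give. It covers the spread between genes, which are not independent replicates, and not that between libraries. Whether a change in RNA processing in the cells or in RNA handling lies behind the lower level was not tested. Of the 60 TEC genes that fell all 60 were called again with GC and length offsets.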
